A study of Mus musculus with 2 samples.

How the data were processed

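Total RNA from the left cerebral cortex of 2 male mice of the hybrid strain B6CASTF1/J, the first-generation cross of C57BL/6J and CAST/EiJ, was sequenced after removal of ribosomal RNA, at 2 months of age. Per the labels, each library started from 300 ng of RNA, ERCC synthetic RNAs were added as spike-ins, and RNA was purified with an animal tissue kit. The labels place both libraries in 1 group and number them replicate 1 and replicate 2. They list separate tissue samples from separately numbered males, and the shared donor record is taken here as a record of the strain.

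Each library came with 3 tables. The deposited gene table and the first deposited transcript table give expected counts, which are estimates of read number that need not be whole, and they were made from an alignment to the transcriptome on build mm10 with GENCODE release M21, per the file headers and the description kept beside them. The deposited TPM values in those tables are transcript abundances scaled to a sum of 1000000 over all rows, spike-ins included. The second transcript table, here called the other quantification, was made directly from the reads of 1 sequence file with the same annotation, per its description, and its estimated counts and TPM were used as deposited. Whether that file held all reads of the library is not given, so the cause of differences between the quantifications stays open. The aligner and the quantification programs are not given in the sources used here. No replicates were pooled by the authors, per the file headers. A hybrid animal carries a CAST/EiJ genome copy while the reference is the C57BL/6J build, and the effect of mismatches on the counts was not measured.

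The depth was 33007629 expected counts in replicate 1 and 32142918 in replicate 2, and 33424292 and 33464140 in the other quantification. A count of 0 allows up to 3 counts, which is 0.0909 and 0.0933 CPM (counts scaled to a library total of 1000000). The gene table has 55536 gene rows, 96 spike-in rows and 26248 rows that name no gene, and the rows without a gene name held 1.78e-05% and 2.48e-05% of the counts. Those rows and the spike-ins were left out of library sizes and comparisons.

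Levels are TPM as deposited, given as mean ± SD over the 2 animals. A gene was called detected at a TPM of at least 1 in both libraries. Expected counts were rounded to whole numbers for the comparison of the animals. Genes with a mean count of at least 10 entered it, and the log2 ratio of replicate 2 over replicate 1 was taken from TMM-normalised CPM with a prior count of 2 (edgeR 4.0.16 in R 4.3.3). The 95% interval of each ratio is the exact conditional binomial interval of Clopper and Pearson, which covers counting error only, since reads without molecular identifiers are not independent molecules. With 1 animal against 1 animal there is no replicate check and no p-value, and an exact sign test over 2 animals cannot go below p = 0.5. Spread between the animals was summarised as the biological coefficient of variation from edgeR's common dispersion. Separate libraries were checked for by a chi-square of the counts over genes.

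In all, 39 gene lists were fixed: 19 lists of markers of cell types and brain regions and 20 lists of function or state. For each list with at least 4 measured members, the median log2 ratio was placed among 10000 random lists of the same size matched on 10 classes of mean expression. The percentile describes these libraries and is not a test of a condition. A list was called outside the random lists below the 2.5th or above the 97.5th percentile. Genes named in the text were chosen by rule: the 10 nuclear protein-coding or long noncoding genes with the highest mean TPM, the 3 most abundant members and the most different member of each list, every member of lists of 5 or fewer, and 20 genes set for transcript forms. The rule also took the 10 genes most different between the animals in each direction at a mean count of at least 100, with a symbol, without predicted models or pseudogenes, and with the same sign in the other quantification. Some are summarised rather than named, and some items that the rule takes are not reported here. The lists, the naming rule, the measures and most alternatives were fixed before the data were examined.

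Genes whose reads are shared with other genes were recognised by a deposited posterior SD above 5% of the count in either library, and identical sequence was measured as the share of a transcript's 31-base words found in the other gene. The SD rule misses some genes of identical sequence. Rn7s1 and Rn7s2 share 100% of their words at a posterior SD of 2.86%, and Gm28661 shares 100% with mt-Co2 at 2.95%. Leaving out genes with shared reads therefore kept these genes. The alternatives tried were DESeq2 1.42.0 size factors, spike-in scaling, TPM with a pseudocount of 1 or 0.1, a prior count of 0.5, no count minimum or a minimum of 100, the other quantification, and leaving out each animal. After the data were seen, 4 alternatives were added: leaving out genes with shared reads (for genes and for lists), matching random lists on transcript length and GC content too, and leaving out members that another list also holds. The procedure was tested on simulated counts for the 18490 genes with a coefficient of variation of 0.0629 put in, and 0.0630 was recovered. Of simulated 2-fold changes 48% and of simulated 4-fold changes 100% gave a ratio of at least 2-fold, against 0.590% of unchanged genes. A simulated 2-fold change lies at the limit itself, so the 48% follows from the limit. Every simulated gene had the same coefficient of variation, while the fifth of genes with the lowest counts had 0.194. The 0.590% is therefore likely too low for genes of low count. All 10 simulated lists shifted by -0.5 were found, and 2 of 30 unshifted lists lay outside. Most lists called outside shifted by less than that, and smaller shifts were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest. Raw reads and allele-specific expression were not analysed here.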

Results

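Transcripts were measured in the left cerebral cortex of 2 male B6CASTF1/J mice aged 2 months, 1 library per animal, with 33007629 expected counts in replicate 1 and 32142918 in replicate 2. Both animals belong to 1 group, so the design implies no comparison between conditions. The values describe which genes the tissue expressed, at what level, and how far the 2 animals differed. Levels are deposited TPM (mean ± SD, n = 2) unless stated otherwise. Coordinates are those of build mm10.

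Among nuclear protein-coding and long noncoding genes, neuronal and nuclear-retained transcripts were among the 10 highest. The synaptic vesicle fusion gene Snap25 (ENSMUSG00000027273.13, chromosome 2, 136713453 to 136782428) was at 1441 ± 9.23 TPM and the kinase gene Camk2a at 1139 ± 60.3. The nuclear long noncoding RNA Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672) was at 5015 ± 771, and the imprinted long noncoding RNA Meg3 at 1187 ± 172. The glycolysis genes Aldoa (1106 ± 61.2) and Gapdh (1104 ± 115) and the chaperone gene Hspa8 (1094 ± 96.9) also belonged to these 10, as did the RNA component Rmrp (ENSMUSG00000115420.1) at 3350 ± 224. A second annotated Rmrp gene (ENSMUSG00000088088.1) overlaps it and was at 1803 ± 165 with shared reads, so the division of reads between them is uncertain. Order and level depended on the quantification: in the other one Gapdh was at 4015 and 3229 TPM, Snap25 at 2264 and 2312, Malat1 at 3026 and 4165 and Rmrp at 0. A pair of long noncoding models on chromosome 17, Gm26917 at 12517 ± 91.7 and Gm42418 at 2251 ± 3.27, lie between positions 39843013 and 39848788, a region known for the Rn45s ribosomal RNA precursor. Across the genome 14989 genes reached at least 1 TPM in both libraries, of which 12934 were protein coding and 294 were long intergenic noncoding RNAs. In the other quantification these numbers were 17008, 13776 and 664.

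A small number of structural RNAs took much of the TPM in the main quantification. The signal recognition particle RNAs Rn7s1 and Rn7s2 and the transcription regulator RNA Rn7sk together held 32.5% of TPM in replicate 1 and 33.5% in replicate 2, but 4.43% and 4.60% of counts. Rn7sk alone was at 58326 ± 3076 TPM, the RNase P RNA Rpph1 at 6983 ± 70.2, the telomerase RNA Terc at 2.08 ± 0.134 and the Y RNA Rny1 at 94.9 ± 54.2. Rny3 had 0 counts in both libraries, which allows up to 0.0909 and 0.0933 CPM. In the other quantification most of these levels nearly vanish, with Rpph1 at 2.45 and 6.80 TPM, Rny1 at 0 and the class of miscellaneous RNAs, which holds Rn7s1, Rn7s2 and Rn7sk, at 0.00320% and 0.0144% of TPM, but Terc was higher, at 6.52 and 3.49 TPM. Mitochondrial genes held 9.58% and 8.88% of TPM, and protein-coding genes 49.4% and 48.1% of TPM and 83.0% and 82.6% of counts. In the other quantification protein-coding genes held 80.3% and 80.4% of TPM, so their sum was higher there. An example is 4426 ± 163 against 2751 ± 59.7 TPM for the summed excitatory neuron markers.

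Markers of glutamatergic neurons gave the highest sum of TPM among the cell types listed. By the median member astrocyte markers were higher, at 63.0 and 57.0 TPM against 49.9 and 49.1 for excitatory neuron markers. The 8 excitatory neuron markers summed to 2751 ± 59.7 TPM, led by Camk2a, the postsynaptic gene Nrgn (849 ± 2.93) and the vesicular glutamate transporter gene Slc17a7 (587 ± 1.08). The 12 inhibitory neuron markers summed to 901 ± 37.8, led by somatostatin (Sst, 197 ± 8.73) and the GABA synthesis gene Gad1 (172 ± 10.04). The ratio of the sums was 3.06 ± 0.195. Sst exceeded parvalbumin (Pvalb) 4.71 ± 0.366-fold, Gad1 exceeded Gad2 3.47 ± 0.198-fold, and Slc17a7 exceeded Slc17a6, the transporter typical of thalamus, 38.3 ± 9.49-fold. Upper layer markers, led by Rasgrf2 (96.8 ± 9.80), Cux2 (83.2 ± 3.44) and Calb1 (65.2 ± 0.205), summed to 335 ± 13.0. Deep layer markers, led by Etv1 (28.4 ± 0.247), Bcl11b (27.5 ± 2.72) and Tle4 (18.6 ± 1.82), summed to 129 ± 9.68, a ratio of 2.61 ± 0.297. In the other quantification the deep layer sum was 210 ± 11.8 and the ratio of upper to deep layer sums 2.06 ± 0.219. The inhibitory sum was 1373 ± 33.0 there, and Gad1 exceeded Gad2 2.54 ± 0.0969-fold.

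Among glia, the 10 astrocyte markers summed to 1591 ± 11.2 TPM, with the glutamate transporter gene Slc1a2 at 758 ± 16.6, Aldoc at 374 ± 9.91 and Slc1a3 at 131 ± 1.16. Mature oligodendrocyte markers summed to 826 ± 118, with the myelin genes Mbp at 330 ± 48.7 and Mobp at 90.1 ± 16.6. Oligodendrocyte precursor markers summed to 94.0 ± 5.53 (Olig1 36.4 ± 3.26), 8.76 ± 0.744-fold less. Microglial markers summed to 216 ± 11.3, with the receptor gene Csf1r at 27.9 ± 1.86. Endothelial markers summed to 167 ± 2.37 (Slc2a1 40.9 ± 0.255), mural cell markers to 74.1 ± 1.01 (Vtn 33.8 ± 0.304) and meningeal fibroblast markers to 92.3 ± 3.90 (Igf2 50.5 ± 3.55). Transcripts typical of blood and of other brain regions were also present. Red blood cell genes summed to 421 ± 59.8, striatal markers to 245 ± 100, claustrum and piriform markers to 220 ± 18.0, thalamic markers to 31.4 ± 3.97, olfactory bulb markers to 12.7 ± 2.11, hippocampal markers to 7.14 ± 1.05 and hypothalamic and midbrain markers to 3.92 ± 1.72. In the other quantification 36 of all 39 list sums were higher by more than the SD, at a median of 1.52-fold over the 39. Of the sums in this paragraph, those more than 1.5-fold higher there were astrocyte (2431 ± 7.66), microglial (327 ± 15.2), endothelial (290 ± 7.59), meningeal (153 ± 2.59), red blood cell (883 ± 130), striatal (379 ± 154), hippocampal (11.3 ± 1.28) and hypothalamic and midbrain (9.23 ± 4.22). Many of these marker genes are also expressed in cortex, and 9 of the 10 striatal markers were at 1 TPM or more in both libraries.

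Glutamate receptor families were each led by a few subunit genes. Among AMPA receptor genes, Gria2, whose subunit limits calcium entry, was at 230 ± 15.7 TPM, 2.24 ± 0.272-fold above Gria1 and 5.01 ± 0.167-fold above Gria4. Among NMDA receptor genes, the obligatory subunit gene Grin1 was at 196 ± 5.37. Grin2b exceeded Grin2a 1.13 ± 0.0162-fold, but in the other quantification the ratio was 0.918 ± 0.0191, so their order was not settled. Kainate receptor genes were led by Grik5 (89.5 ± 2.96) and metabotropic glutamate receptor genes by Grm5 (90.7 ± 2.46). GABA-A receptor genes summed to 829 ± 23.9 and sodium channel genes to 839 ± 17.6. The pore-forming sodium channel gene Scn2a (136 ± 1.15) was 2.60 ± 0.0534-fold above Scn1a, and 2.84 ± 0.0591-fold in the other quantification. As a sum, AMPA receptor genes stood 2.99 ± 0.0805-fold above kainate receptor genes.

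**Figure D1:**
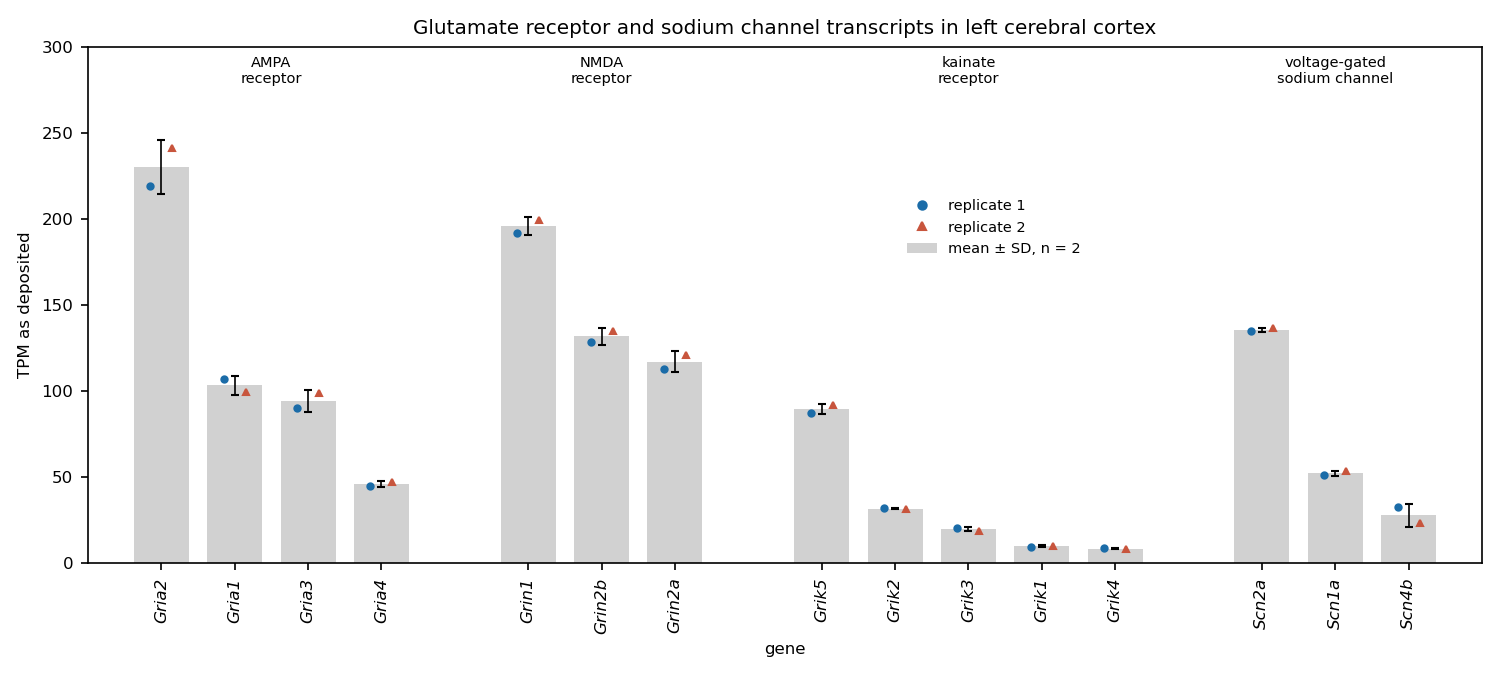
TPM as deposited of named glutamate receptor and sodium channel subunit genes, with 1 point per animal and bars giving the mean with its SD (n = 2). The highest bar among those drawn is Gria2 (230 TPM) for AMPA, Grin1 (196) for NMDA and Grik5 (89.5) for kainate receptor genes, and Scn2a (136) for sodium channel genes. Only some of the 8 sodium channel genes are drawn, and Scn2a is not the highest of the 8.

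Synaptic, peptide and modulator genes were also led by a few members. The 14 vesicle and release genes summed to 6191 ± 110 TPM, with Syp at 856 ± 43.6 after Snap25, and the 10 postsynaptic genes summed to 3639 ± 87.1, with Dlg4 at 361 ± 0.481. Camk2a exceeded Camk2b 4.16 ± 0.356-fold. Among neuropeptide genes, cholecystokinin (Cck, 340 ± 3.43), Sst and neuropeptide Y (Npy, 89.1 ± 7.59) led. Among monoamine and acetylcholine receptors, the muscarinic receptor gene Chrm1 led at 67.8 ± 0.955, followed by Chrm3 at 24.6 ± 0.446 and the adrenergic receptor gene Adrb1 at 19.6 ± 1.41. Imprinted genes were led by Meg3, Rian (548 ± 27.2) and Snrpn (405 ± 14.6). The Y-linked genes Ddx3y (21.9 ± 0.559), Eif2s3y (22.1 ± 6.87), Kdm5d (8.19 ± 1.67) and Uty (10.7 ± 0.488) were expressed and Xist was at 0.01 TPM in each library, in libraries that the labels give as male. Interferon response genes summed to 39.5 ± 1.65, of which Ifi27 made 24.8 ± 1.41.

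As listed in the main quantification, mitochondrial mRNAs were led by mt-Co1 (5891 ± 505 TPM), mt-Cytb (3097 ± 104) and mt-Nd1 (3058 ± 303). In the other quantification mt-Atp6, at 8522 and 6262 TPM, was above mt-Cytb (5022 and 4870), so this order was not settled. The gene mt-Co2 was listed at only 308 and 168 TPM, while the nuclear pseudogene Gm28661 (chromosome 1, 24614885 to 24615565), which holds 100% of its 31-base words in common with mt-Co2, was at 6617 ± 359. Gm10925 shares 100% of its words with mt-Atp6, Gm28437 100% with mt-Co3, and Gm29216 97.2% with mt-Co1. These 4 pseudogenes held 19579 and 18310 TPM. The division of reads between each pair is therefore uncertain, as it is for the hemoglobin genes Hba-a1 and Hba-a2, where 75.4% and 92.6% of words were shared.

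Transcript forms of the 20 genes set for this purpose were read from both quantifications, and the leading transcript was the same in 18, the exceptions being Pkm and Grin1. The amyloid precursor gene App was expressed mainly as App-201, the form of 695 amino acids with 16 exons, at 92.8 ± 0.323% of the gene's TPM (91.2 ± 0.198% in the other quantification). The tau gene Mapt gave mainly Mapt-204 of 372 amino acids (73.1 ± 0.323%), Camk2b mainly Camk2b-209 (90.3 ± 1.07%) and Snap25 mainly Snap25-201 (84.5 ± 0.693%). Of Ntrk2, the neurotrophin receptor gene, forms encoding 821 amino acids made 55.2 ± 1.59% and forms of 476 amino acids made 31.3 ± 1.37%. The clathrin light chain gene Clta was led by Clta-205 (72.8 ± 0.522%) and Cdc42 by Cdc42-201 (61.2 ± 0.541%). AMPA receptor genes were led by Gria1-201 (60.7 ± 0.788%), Gria2-202 (54.8 ± 0.737%), Gria3-201 (60.3 ± 1.39%) and Gria4-203 (53.8 ± 1.14%). The first of these forms encode 907, 883 and 888 amino acids, but Gria4-203 only 433. The Gria4 forms of 902 amino acids, Gria4-201 and Gria4-202, made 29.8 ± 2.63% and 13.5 ± 0.0810%. Homer1 had no form above Homer1-207 at 31.6 ± 1.29%. The share of the leading form depended most on the quantification for Mbp and Dlg4, at 67.7 against 33.3% for Mbp-211 and 57.0 against 28.8% for Dlg4-203. Other shares also moved, among them Clta-205 (72.8 against 59.2%), Gria3-201 (60.3 against 68.6%) and Cdc42-201 (61.2 against 55.8%).

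The 2 animals were close, and the genes that differed most included markers of striatum and the choroid plexus gene Ttr. Ttr, which encodes transthyretin (ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321), was 10.3-fold higher in replicate 2, at 8.58 and 89.2 TPM (log2 ratio 3.37, 95% interval 3.17 to 3.59). The dopamine receptor gene Drd2 (ENSMUSG00000032259.8, chromosome 9, 49340627 to 49408177) was 4.14-fold higher in replicate 1 (log2 ratio -2.05, interval -2.45 to -1.72), and the adenosine receptor gene Adora2a was 3.50-fold higher there (log2 ratio -1.81). Also lower in replicate 2 were Lrrc10b (-1.51), Tac1 (-1.37), Rgs9 (-1.14), Syndig1l (-1.06) and Ptger3 (-1.01). Higher in replicate 2 were Tnfrsf25 (1.20), the activity-regulated gene Arc (0.89), Ccn4 (0.80), Cfp (0.79), Csrnp1 (0.76), Lncpint (0.74), Nr4a1 (0.72) and AC154542.1 (0.72). The naming rule also gave Pagr1a (-2.07), Gemin4 (-1.28) and both annotated Nnt genes, whose reads are shared with other genes, so their ratios are uncertain. One Nnt gene (ENSMUSG00000116207.1) had 368 counts in replicate 1 and 0 in replicate 2, and the other (ENSMUSG00000025453.18) gave 1.17.

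Of 18490 genes with a mean count of at least 10, 333 differed at least 2-fold between the animals, 206 higher and 127 lower in replicate 2, and 4213 differed by more than counting error. With spike-in scaling the count was 633, 563 higher and 70 lower, and with TPM and a pseudocount of 1 it was 80, 38 higher and 42 lower. Spike-ins made 0.428% and 0.345% of counts, and scaling by them moved the median log2 ratio of all genes from -0.0029 to 0.32, so list differences are given relative to other genes. At a mean count of at least 100, 29 of 12817 genes differed 2-fold, 12 higher and 17 lower, and 17 of them had shared reads. The libraries correlated across 28250 genes with Pearson r = 0.992 on log2(TPM + 1) and Spearman rho = 0.955. These values are across genes, which are not independent replicates. The coefficient of variation between the animals was 0.0629, and it was 0.194 in the fifth of genes with the lowest counts and 0.0454 in the fifth with the highest. Chi-square over degrees of freedom was 6.42, so the libraries differed by more than sampling noise and were not merged. This does not show that they came from separate animals, which is taken from the labels.

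Striatal markers were lower in replicate 2 as a group. All 10 were lower, 9 by more than counting error, with a median log2 ratio of -1.02 (percentile 0 of the random lists). The group includes the dopamine signalling gene Ppp1r1b (-0.69), the enkephalin gene Penk (-0.89) and the D1 receptor gene Drd1 (-0.73). Claustrum and piriform cortex markers were lower for 5 of 5, namely Nr4a2 (-0.64), Lxn (-0.42), Synpr (-0.25), Ntng2 (-0.18) and Gng2 (-0.11), with a median of -0.25 (percentile 0). Thalamic markers had a median of -0.20 (percentile 1.78, but 11.97 with TPM and a pseudocount of 1), with Slc17a6 at -0.28 and Prkcd at -0.32. Olfactory bulb markers had a median of -0.33 over 4 genes (percentile 0.78, but 3.81 with matching on length and GC), among them Cdhr1 (-0.24) and Trh (-0.39), and hypothalamic and midbrain markers had -0.72 over 4 genes of low count (percentile 0.46). Hippocampal markers did not stand apart (-0.17, percentile 9.09; C1ql2 -0.59). With spike-in scaling the claustrum and thalamus medians were above 0, at 0.07 and 0.12, but 0.24 and 0.20 below the median of all genes, and the olfactory bulb median was -0.01 with 2 genes higher and 2 lower.

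Among lists for cortical cell types, mature oligodendrocyte and deep layer markers were lower in replicate 2, and neuronal markers in general were close to 0. Of 10 mature oligodendrocyte markers 9 were lower by more than counting error (median -0.27, percentile 0), including Mbp (-0.26) and Ermn (-0.33). Of 10 deep layer markers 9 were lower, 6 by more than counting error (median -0.23, percentile 0), including Foxp2 (-0.78), Bcl11b (-0.26) and Tle4 (-0.20). Foxp2 and Bcl11b are also known as genes of striatal neurons, and this shift was not separated from the striatal one. Upper layer markers had a median of 0.03 (percentile 85.5) and excitatory neuron markers 0.02 (percentile 85.1). Inhibitory neuron markers had -0.07 (percentile 4.92; Lhx6 -0.32), astrocyte markers -0.04 (percentile 26.6; Gfap -0.25) and microglial markers -0.08 (percentile 5.40). Oligodendrocyte precursor markers had -0.12 (percentile 2.11, but 4.01 with TPM and a pseudocount of 1), with C1ql1 at -0.46. Endothelial (0.03, percentile 80.2), mural (0.10, percentile 95.5) and meningeal markers (0.03, percentile 72.2) did not stand apart. Choroid plexus and ependyma markers had 0.28 over 5 genes (percentile 97.6), of which Ttr (3.37) and Kl (0.28) exceeded counting error. This list was inside the random lists with TPM and a pseudocount of 1 (percentile 91.9), in the other quantification (94.8), without shared reads (96.4) and with matching on length and GC (96.7), so the call is weak. Red blood cell genes had -0.26 (percentile 0.065), with Hba-a1 at -0.43, Hba-a2 at -0.26, Hbb-bs at -0.13, Hbb-bt at -0.48 and Alas2 at 0.12. With spike-in scaling the oligodendrocyte (0.06), deep layer (0.09), precursor (0.20) and red blood cell (0.06) medians were above 0, and 0.26, 0.22, 0.11 and 0.25 below the median of all genes.

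**Figure D2:**
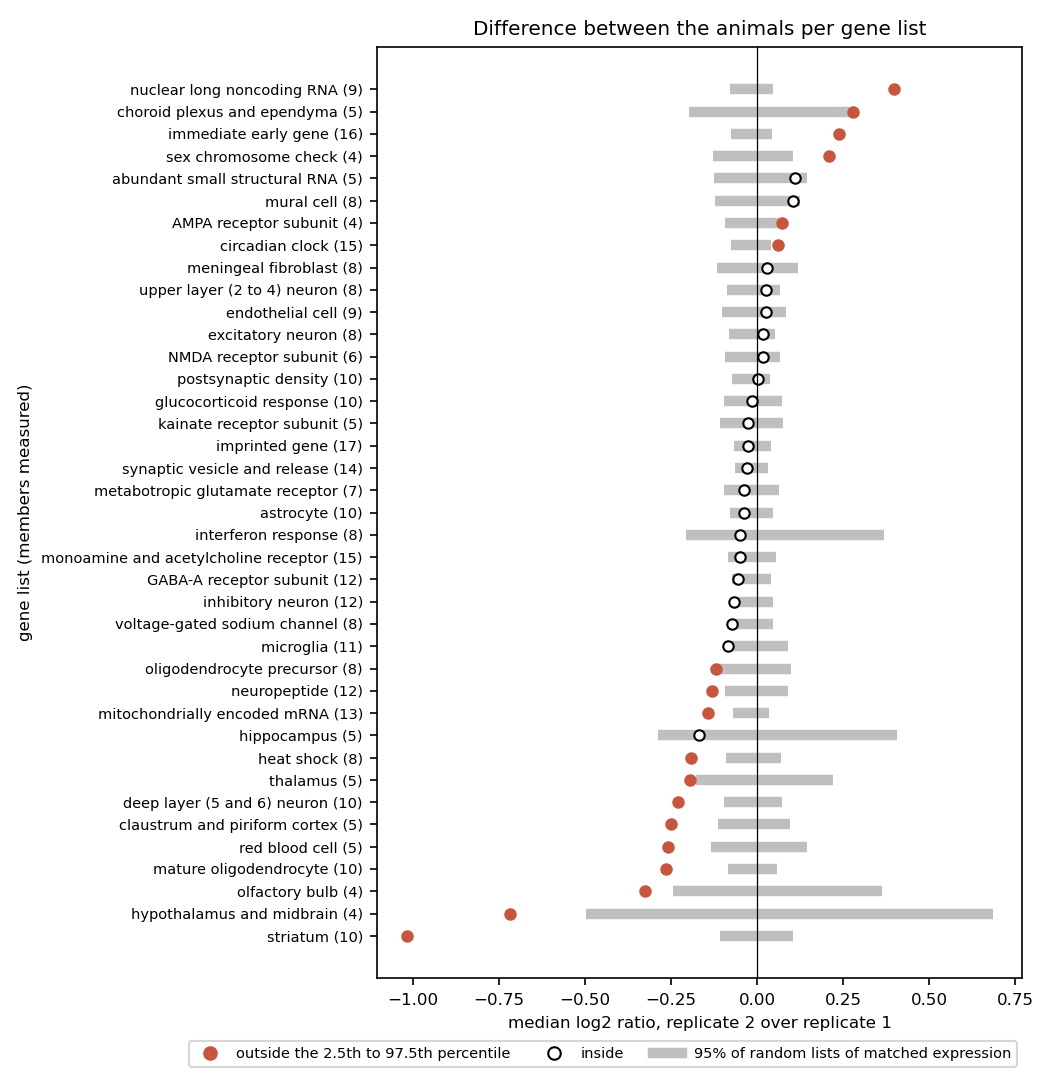
Median log2 ratio of replicate 2 over replicate 1 for each gene list (number of measured members in brackets), with grey bars holding 95% of random lists of matched expression. Of 39 lists 18 lie outside, 6 higher and 12 lower in replicate 2, from striatum (-1.02) to nuclear long noncoding RNA (0.40), and 9 of the lower lists have medians above 0 under spike-in scaling.

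Activity-regulated genes and nuclear noncoding RNAs were higher in replicate 2. Of 16 immediate early genes 14 were higher, 11 by more than counting error (median 0.24, percentile 100), including Arc, Nr4a1 (0.72), Fos (0.67), Egr2 (0.62) and Dusp1 (0.60). The abundant members Egr1 and Egr3 were at 0.20 and 0.14, and Jun was at -0.08. All 9 nuclear long noncoding RNAs were higher by more than counting error (median 0.40, percentile 100), with Malat1 at 0.42 (interval 0.42 to 0.43), Meg3 at 0.40, Neat1 at 0.46 and Snhg14 at 0.22. Of 15 circadian clock genes 9 were higher, 6 by more than counting error, and 6 lower, none by more (median 0.06, percentile 99.6), with Per1 at 0.43, Ciart at 0.39, Per3 at 0.26 and the output gene Dbp at 0.06. The sex chromosome list had 0.21 (percentile 99.9), from Eif2s3y (0.69) and Kdm5d (0.41), with Ddx3y at -0.03 and Uty at 0.01, but in the other quantification, where Xist is added, it had 0.01 (percentile 70.2).

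Heat shock and mitochondrial transcripts were lower in replicate 2 as groups. Of 8 heat shock genes 7 were lower, 6 by more than counting error (median -0.19, percentile 0), including Hspa8 (-0.16), Hsp90aa1 (-0.19), Hsph1 (-0.19) and Hspa1b (-0.41). Of 13 mitochondrial mRNAs 12 were lower by more than counting error (median -0.14, percentile 0), and mt-Atp8 was at 0.35. In the other quantification 8 of 12 were lower and 4 higher (median -0.11, percentile 0.51), so single mitochondrial genes were not settled. With spike-in scaling the heat shock and mitochondrial medians were 0.13 and 0.18, which is 0.18 and 0.13 below the median of all genes. Glucocorticoid response genes (-0.01, percentile 50.6; Sgk1 0.26) and interferon response genes (-0.05, percentile 20.7) did not stand apart. Imprinted genes (-0.03, percentile 36.8; Dlk1 -0.84) and small structural RNAs (0.11, percentile 94.9) did not in the main comparison. They lay outside in 1 alternative each, at percentile 0.40 without members of another list and at 99.6 with matching on length and GC.

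**Figure D3:**
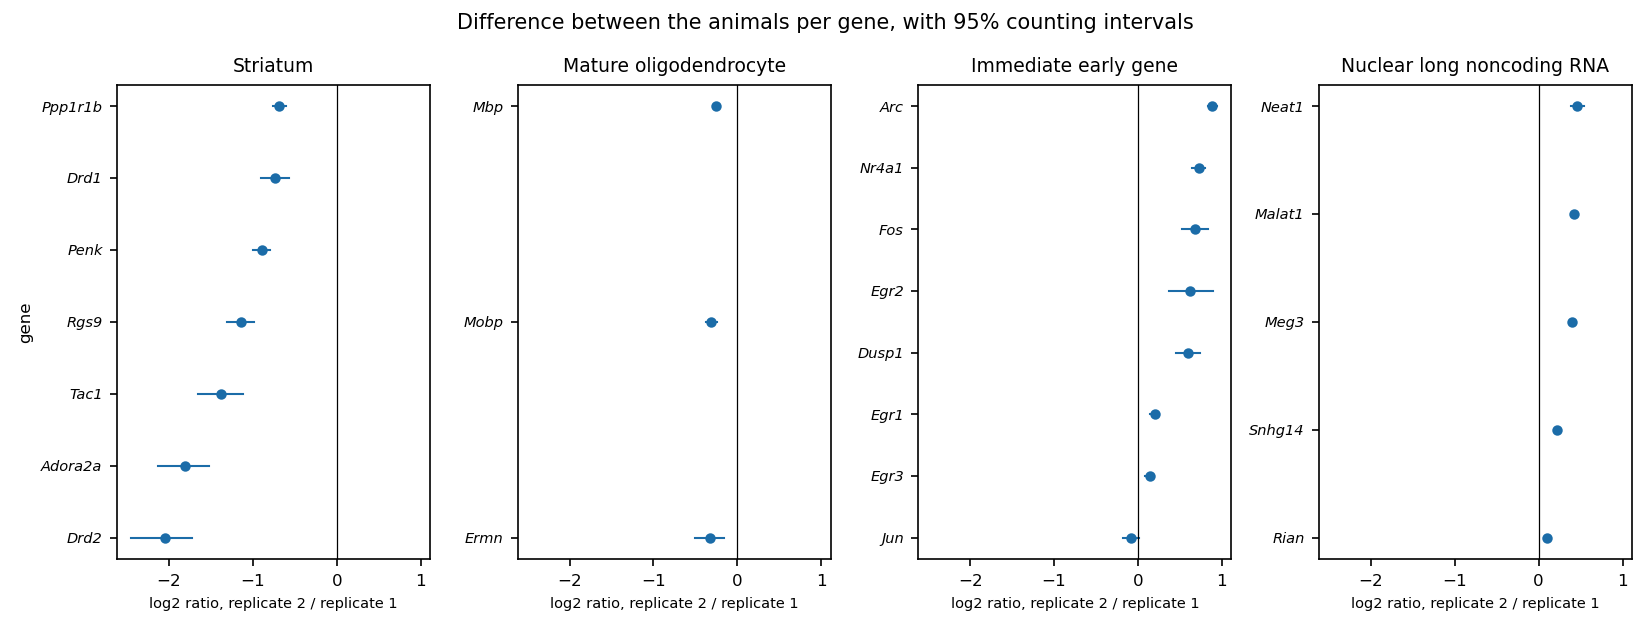
Log2 ratio of replicate 2 over replicate 1 for named genes of 4 lists, with bars giving 95% counting intervals. The striatal and oligodendrocyte markers drawn lie below 0. The immediate early genes drawn, except Jun (-0.08), and the nuclear long noncoding RNAs drawn lie above it. Not all members are drawn. Over the whole lists, 1 of 10 oligodendrocyte markers was higher and 2 of 16 immediate early genes were lower in replicate 2. The oligodendrocyte median lies above 0 (0.06) under spike-in scaling.

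Receptor, channel and synapse lists differed little between the animals. AMPA receptor genes had a median of 0.07 (percentile 98.0, but 96.4 with matching on length and GC), with Gria3 at 0.13, Gria2 at 0.10, Gria4 at 0.05 and Gria1 at -0.08. NMDA receptor genes had 0.02 (percentile 80.6), with Grin2b at 0.14. Kainate receptor genes had -0.02 (percentile 45.8), from Grik1 at 0.04 to Grik3 at -0.12, with Grik5 at 0.02, Grik2 at -0.02 and Grik4 at -0.05. Metabotropic glutamate receptor genes had -0.04 (percentile 33.6; Grm4 -0.26), GABA-A receptor genes -0.05 (percentile 9.48; Gabra5 -0.16) and sodium channel genes -0.07 (percentile 3.84, and 2.05 with matching on length and GC; Scn4b -0.50). Vesicle and release genes had -0.03 (percentile 35.3; Cplx1 -0.09), postsynaptic genes 0.00 (percentile 79.1; Camk2a 0.10) and monoamine and acetylcholine receptors -0.05 (percentile 16.4). Neuropeptide genes had -0.13 (percentile 0.38), with 11 of 12 lower and 7 by more than counting error, and with spike-in scaling 0.19, which is 0.12 below the median of all genes. Nts (-1.64), a gene with a mean count below 100, differed most among them, and Penk and Tac1 are also in the striatal list. Without members that another list also holds the neuropeptide median was -0.02 (percentile 35.1), and the list was also inside in the other quantification (3.02) and with matching on length and GC (5.17).

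The 2 quantifications of each library gave similar counts for long genes and different ones for short genes. Across the 18490 genes the median log2 ratio of the other quantification over the main one was 0.09 in replicate 1 and 0.13 in replicate 2, with Spearman rho of 0.970 in both. At least 4-fold differences occurred in 663 and 651 genes. Of genes under 300 nucleotides, 98.7% and 97.3% had no counts in the other quantification, Rmrp among them, and Rn7sk had 0 and 3 counts there. From 1000 to 2000 nucleotides the median ratio of counts was 1.00 and 1.04, and at 4000 or more 1.09 and 1.12. The spike-ins, whose sequences are not part of the mouse genome, shared the trend with length but were lower in the other quantification in every length class (by median). Over 24 of them in each library the ratio rose with length (Spearman rho 0.824 and 0.862, across spike-ins), from 0.518 and 0.545 under 600 nucleotides to 0.759 and 0.825 at 1000 nucleotides or more.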

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

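No test in this part was chosen after its result was seen, since both values are plain counts. The rows of the gene tables that name no gene were outside the measurements used here, and they held 6 counts in replicate 1 and 8 in replicate 2, which is more than the 3 counts that a count of 0 allows. These counts are spread over 26248 rows. No single row reached 3 counts in replicate 1, and 1 row did in replicate 2, at 3.98 counts. No explanation was tested.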

How the results depend on the processing

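Leaving out genes with shared reads, matching on transcript length and GC content, and leaving out members of another list were chosen only after the main results were seen. Of the list medians recomputed under an alternative, 250 stayed inside the random lists, or outside them with the same sign. Of these 18, all inside, changed sign, 13 of them with spike-in scaling. Direction and side were kept by every value for the striatum, mature oligodendrocyte, immediate early gene and nuclear long noncoding RNA lists except the oligodendrocyte value with spike-in scaling. Spike-in scaling, which moved all genes by 0.32, turned 22 medians from below to above 0, of which 9 were called outside: deep layer 0.0937, mature oligodendrocyte 0.0569, oligodendrocyte precursor 0.20, red blood cell 0.0649, thalamus 0.12, claustrum and piriform cortex 0.0711, heat shock 0.13, mitochondrial mRNA 0.18 and neuropeptide 0.19. These 9 stayed outside on the low side, as the common shift implies. Medians no longer outside were, with TPM and a pseudocount of 1, precursor -0.11, choroid plexus 0.16 and thalamus -0.10. In the other quantification they were choroid plexus 0.29, neuropeptide -0.10 and the sex chromosome list 0.012, where Xist enters as an added member. Without genes with shared reads choroid plexus (0.28) was inside, and with matching on length and GC so were choroid plexus (0.28), olfactory bulb (-0.33), AMPA receptor (0.0741) and neuropeptide (-0.13). Without members of another list neuropeptide was at -0.0217. Medians newly outside were imprinted genes without members of another list (-0.0991), and small structural RNAs (0.1117) and sodium channels (-0.0731) with matching on length and GC. The cause was not tested, apart from the common shift and the added member. The hypothalamus and small structural RNA lists have no value in the other quantification, nor mitochondrial mRNAs with length and GC matching. At a minimum count of 100 only 33 of the 39 lists have a value. Those without one are choroid plexus, hippocampus, hypothalamus, olfactory bulb, interferon response and small structural RNA. Without members of another list, 10 lists have a value. The count of 2-fold genes, 333, became 633 with spike-in scaling, 80 with TPM and a pseudocount of 1, 1958 with no count minimum, 29 at a minimum of 100 and 209 without shared reads, and the last 3 follow from the genes tested. Detected genes numbered 8525 at 10 TPM, and 15413 to 15729 with 1 animal left out. The coefficient of variation, 0.0592 to 0.0736 otherwise, was 1e-04 as the square root of the median DESeq2 gene-wise dispersion, which is the root of that tool's lowest value. Grin2b over Grin2a was 0.918 in the other quantification, which turned their order. Other ratios kept their order but moved there, such as Gad1 over Gad2 (2.54 ± 0.0969), upper over deep layer sums (2.06 ± 0.219), Scn2a over Scn1a (2.84 ± 0.0591) and Sst over Pvalb (5.46 ± 0.571). Of the 39 list sums, 37 moved by more than the SD in the other quantification (36 higher, median 1.52-fold) and 28 when rescaled without mitochondrial genes and spike-ins (27 higher, median 1.11-fold). No paired analysis was possible because there is 1 group. The coefficient of variation was highest, at 0.194, in the fifth of genes with the lowest counts, and the part of depth in this was not tested.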

Other observations

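In this part the tests of library scaling and both tests of shared reads were chosen only after the result was seen, and the test of length and GC content and the second gene lists were written after the patterns were seen but before their own values were. Several classes of RNA had median log2 ratios above 0. The median was 0.41 over 55 small nucleolar RNAs, 0.37 over 24 small nuclear RNAs, 0.33 over 147 sense intronic transcripts and 0.33 over 1370 transcripts still to be experimentally checked (the class TEC), against -0.02 over 14639 protein-coding genes. Long intergenic noncoding RNAs had 0.06 over 575 genes. Small nuclear RNAs made 1.83% of TPM in replicate 1 and 2.52% in replicate 2, and small nucleolar RNAs 0.685% and 0.868%. These medians were not set against random lists, and small nuclear and small nucleolar RNAs had almost no TPM in the other quantification, so their values rest on 1 quantification.

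Striatal markers were lower in replicate 2 (median -1.02). A common scaling moves all lists alike, and the excitatory neuron list was at 0.0186. TMM scaling centres typical genes near 0, so that median was largely set in advance and cannot by itself decide on scaling or depth. Under spike-in scaling the striatal median was -0.70, against 0.32 for all genes. Shared reads are argued against by the posterior SD, which exceeded the limit in 0 of the list's members. A second striatal list of 14 measured genes, 11 of them at 1 TPM or more in both libraries, had a median of -0.31 (percentile 0) with 13 lower, from Slc35d3 (-1.48) to Arpp21 (0.02), a gene also abundant in this cortex at 331 and 337 TPM. These values are consistent with the hypothesis of less striatal tissue in the replicate 2 dissection. Lower expression of the same genes within a like amount of tissue stays open, and no biological explanation was tested because the design has 1 group.

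Ttr was higher in replicate 2 (log2 ratio 3.37). Shared reads are argued against by a posterior SD of 0% of the Ttr count. A second list of 9 choroid plexus genes lay at percentile 99.99 with a median of 0.86 and all 9 higher, though Aqp1, Prlr and Col8a1 did not exceed counting error. None of them was at 1 TPM or more in both libraries. Slc4a5 was at 2.48 and Cldn2 at 1.61, so a trace of choroid plexus in the replicate 2 library may be a source. Levels were low, at 0.57 TPM for Slc4a5 against 89.2 for Ttr in replicate 2, and Kcnj13 (0.23) and Clic6 (0.34) of the first list did not exceed counting error. The size of any such share stays open, and no biological explanation was tested.

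Nuclear long noncoding RNAs were higher in replicate 2 (median 0.40). The list was at percentile 100 among protein-coding lists matched on expression, length and GC content in 5 classes of each. The outer classes have no limit, so a very long member may be set against shorter genes. The value argues against length and GC content as the whole cause only as far as these classes match them. A second list of 11 nuclear long noncoding RNAs had a median of 0.12 (percentile 99.6), with 7 higher, such as Mir124a-1hg (0.42) and Dleu2 (0.37), and 4 lower, such as Tug1 (-0.09). A larger share of nuclear RNA in replicate 2 may account for part of the difference, as a hypothesis, but the second list moved less than the first and in both directions. RNA quality and differences between the animals stay open, and no biological explanation was tested.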
